A study of Mus musculus with 2 samples.

How the data were processed

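RNA was measured in 2 libraries of naturally ovulated MII oocytes of ICR mice, 1 from young females of 3 months and 1 from aged females of 12 months, each a pool of 18 oocytes. Per the labels' protocols, the oocytes were lysed together and mRNA was reverse transcribed from an adaptor primer with an oligo(dT) stretch of 24 bases. A poly(A) tail was then added to the cDNA, the second strand was made from another oligo(dT) primer, and the cDNA was amplified by 18 and then 14 cycles of PCR and sequenced on a SOLiD instrument. Per the submitters' processing notes the genome build was mm9. The aligner, the counting program and the annotation release are not given in the sources used here. Neither are the treatment of reads that map to several places and the use of strand. Genes with near-identical copies (ribosomal protein, tubulin, Nlrp and Obox genes, mitochondrial genes with nuclear copies) and genes that overlap another gene, such as small nucleolar RNAs within host genes, are therefore uncertain. The amplification used no molecular identifiers, so reads are not independent molecules, and all intervals and floors cover counting error only.

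The deposited values form 1 table of 36227 Ensembl genes with the chromosome of each. Whole-number counts per gene and library are given for 18364 genes as deposited by the authors, and they are unnormalized, since they sum to 19475110 for the young and 18597656 for the aged library. The other 17863 genes have no count in either column. The authors' deposited log2 fold changes are young over aged, without and with scaling to the library totals. The scaled values differed from the unscaled ones by a median of −0.0665, the log2 ratio of the young to the aged total being 0.0665. Recomputed from the counts, all 15387 unscaled fold changes matched within 1e-06. In 1028 of them the authors had replaced a count of 0 by 0.5, and 2977 counted genes, with 0 counts in a library and few in the other, have no fold change. The authors' deposited score (a z value per gene), p-value and q-value columns compare reads of 1 library per age, and the program that made them is not given in the sources used here. These columns were used only for the number of genes the authors marked (p below 0.001) and for Bub1b.

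Symbols came from the gene names of GENCODE mouse release 21, which matched 85.5% of all rows and 93.7% of the counted rows by Ensembl ID. Length and GC content are those of each gene's longest protein-coding transcript in that release, or of its longest transcript of any type. Both were found for 97.0% of the genes above the floor. That release describes another build than mm9, so no coordinates are given, and chromosomes are those of the deposited table. Every row has an Ensembl gene ID, rows without a symbol stay in the totals and counts of genes, and no column belongs to another sample.

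The ratio of each gene is log2 of aged over young after scaling to the library totals. Genes with a mean of at least 20 counts over both libraries were kept, 10211 in all. Where a library had 0 counts, 3 counts were set in its place, and such folds are written as at least that size. They hold against 3 counts only, since the 95% counting interval can begin nearer to equality. Its near end is given beside them. With 1 library per age there is no estimate of the spread between animals or libraries, so no test was run and genes are described by a rule of size, 2-fold. A stricter count requires that the 95% exact (Clopper-Pearson) interval of the ratio, from the aged share of a gene's counts, also lies beyond 2-fold. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. TMM factors, 0.878 for the young and 1.14 for the aged library, came from edgeR 4.0.16 in R 4.3.3, which was used for nothing else.

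Before the data were examined, 22 gene lists were fixed for the oocyte and its ageing, with markers of the cells that surround oocytes. The median log2 ratio of a list's members above the floor was placed as a percentile among those of 10000 random lists of the same size, matched on mean count in 20 bins. A list is said to stand apart below percentile 2.5 or above 97.5. Of the 22 lists 9 did so, 4 low and 5 high, where 5% of lists of genes drawn singly at random lie outside. Members of a list can vary together, and some lists share genes, such as Hspa9 and Hsf1. The number outside is therefore no measure of an excess over chance. A shift of all genes by the scaling does not alter these percentiles. A matching of each member to its 100 nearest genes in mean count, transcript length and GC content was added after the data were seen, and 7 lists, 4 low and 3 high, stood apart with it. Also added was a correction that takes from each ratio the median of its bin, among 10 bins of length by 10 of GC content.

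Genes named in the text were chosen by a rule fixed before the data were examined. It takes Bub1b, up to 3 members of each list with the largest difference, the 10 highest and 10 lowest genes by the bound of the interval nearest to equality, leaving out clone names, and the 5 most abundant genes of each library. It gave 91 different genes. The alternatives listed at the same time were other scalings (median-centring, TMM, totals without the 100 most abundant genes), 0.5 or 5 counts added, no floor or a floor of 100 counts, sizes of 1.5-fold and 4-fold, sums over rows sharing a symbol, random lists not matched on expression, and a q-value of 0.0001 for the authors' calls. The closing section gives their effect.

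The calculation was tested on simulated counts with the genes and totals of the aged against young comparison. Of 97 genes simulated with a 3-fold difference 99.0% passed 2-fold, and 82.5% also by the interval. Of 98 genes with a 1.5-fold difference 2.04% passed 2-fold, and of 10009 unchanged genes 0.140%. The intervals held the true ratio for 96.9%, 94.9% and 95.9% of these genes. All 20 lists lowered by 0.5 on the log2 scale fell below the range, and 7 of 100 unchanged lists of 25 genes lay outside it. These simulations hold counting error only, without the variation of animals, pooling and amplification. Unchanged simulated genes had a median absolute log2 ratio of 0.08, while the real genes had quartiles of −0.28 and 1.09. The result for the 20 lowered lists therefore does not show that a shift of 0.5 would be found in these data.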

Results

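RNA was measured in mature mouse oocytes arrested at metaphase of the second meiotic division (MII) that females of the ICR strain had ovulated naturally. Each age was represented by 1 library made from 18 pooled oocytes of 6 females, with 3 oocytes from each. The young females were 3 months old and the aged females 12 months old. The young library held 19475110 counts and the aged library 18597656. At least 1 count was recorded for 16317 genes in the young library and 16406 in the aged library, and at least 20 counts for 9906 and 10236. A count of 0 allowed up to 0.154 CPM (counts scaled to a common library total) in the young library and 0.161 CPM in the aged one. With 1 library per age, no difference below has a replicate check, and no p-value for age was computed. The comparisons describe these 2 pools, by the size of the difference and by 95% intervals that cover counting error only. The study's title names BubR1, the product of Bub1b, as protecting ageing oocytes from aneuploidy, and the comparison asks how the oocyte transcriptome differed between the ages.

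The most abundant transcript of both libraries was Gdf9, a growth factor secreted by the oocyte, with 97099 CPM in the young library and 42795 CPM in the aged one, a level 2.27-fold lower. H1foo, the oocyte linker histone, was 1.36-fold lower in the aged library, Tcl1 1.78-fold lower, Bcl2l10 1.83-fold lower and the oocyte-secreted protein gene Oosp1 2.13-fold lower. Pttg1, which encodes securin, the inhibitor of separase, was the third most abundant gene of the aged library with 26808 CPM against 5430 CPM, 4.94-fold higher. Bpgm, among the 5 most abundant genes of the aged library, had 12887 CPM against 13975 CPM. The 5 most abundant genes took 21.6% of the counts in the young library and 14.0% in the aged library, and the 100 most abundant took 51.1% and 40.6%. Across genes, which are not independent replicates, Pearson's r between the log10 CPM of the libraries was 0.89.

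Of 10211 genes with a mean of at least 20 counts, 2844 were at least 2-fold higher in the aged library and 1081 at least 2-fold lower when counts were scaled to the library totals. The counting interval also lay beyond 2-fold for 1841 and 648 of them. The median log2 ratio of aged over young was 0.43, with quartiles of −0.28 and 1.09, and 66.4% of genes had a ratio above 0. After centring on the median gene, 1633 genes were at least 2-fold higher and 1766 lower. With scaling by the trimmed mean of M-values (TMM) there were 1757 and 1668, and with totals that left out the 100 most abundant genes 1991 and 1489. Genes at least 2-fold apart were therefore 72.5% higher with library totals, and 48.0%, 51.3% and 57.2% higher with these scalings. Values below are given for library totals, and list medians also relative to the median gene, which lowers each by 0.43. The authors' deposited table marked 5295 genes as higher in the aged library and 2406 as lower at p below 0.001. In the authors' deposited table, 3058 of these calls were smaller than 2-fold, and its p-values compare the reads of 2 libraries, not the ages.

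**Figure D1:**
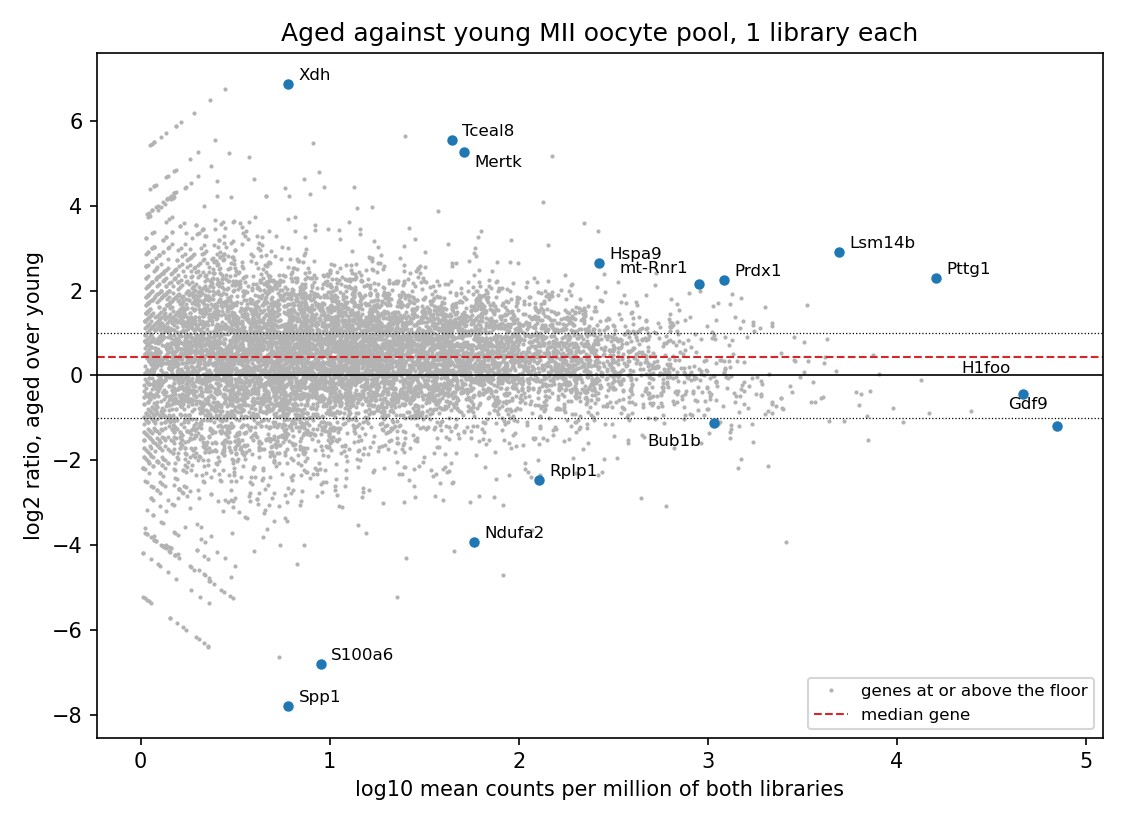
Each point is 1 of the 10211 genes with a mean of at least 20 counts, placed by its log10 mean CPM over both libraries (x axis) and its log2 ratio of aged over young (y axis). The dashed line is the median gene at 0.43 and the dotted lines mark 2-fold. Bub1b lies at −1.13 and Pttg1 at 2.30, and genes with a count of 0 in a library are drawn at their bound of 3 counts.

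The ratio depended on the base composition of the transcript. The decile of genes with the lowest GC content (27.5% to 41.8%) had a median log2 ratio of 1.04, and the decile with the highest (57.7% to 73.8%) had −0.28, which is −0.71 relative to the median gene. Spearman's rho with GC content was −0.40 across 9902 genes, and with transcript length it was 0.14. The decile of shortest transcripts had a median of −0.01, −0.44 relative to the median gene, and the decile of longest transcripts 0.70. After each gene's ratio was reduced by the median of its length and GC bin, 1345 of the 9902 genes were at least 2-fold higher and 1477 at least 2-fold lower. That correction also centres the genes, and median-centring alone gave 1633 and 1766 of 10211. Each gene list below is therefore also compared with random lists matched on mean count, transcript length and GC content.

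**Figure D2:**
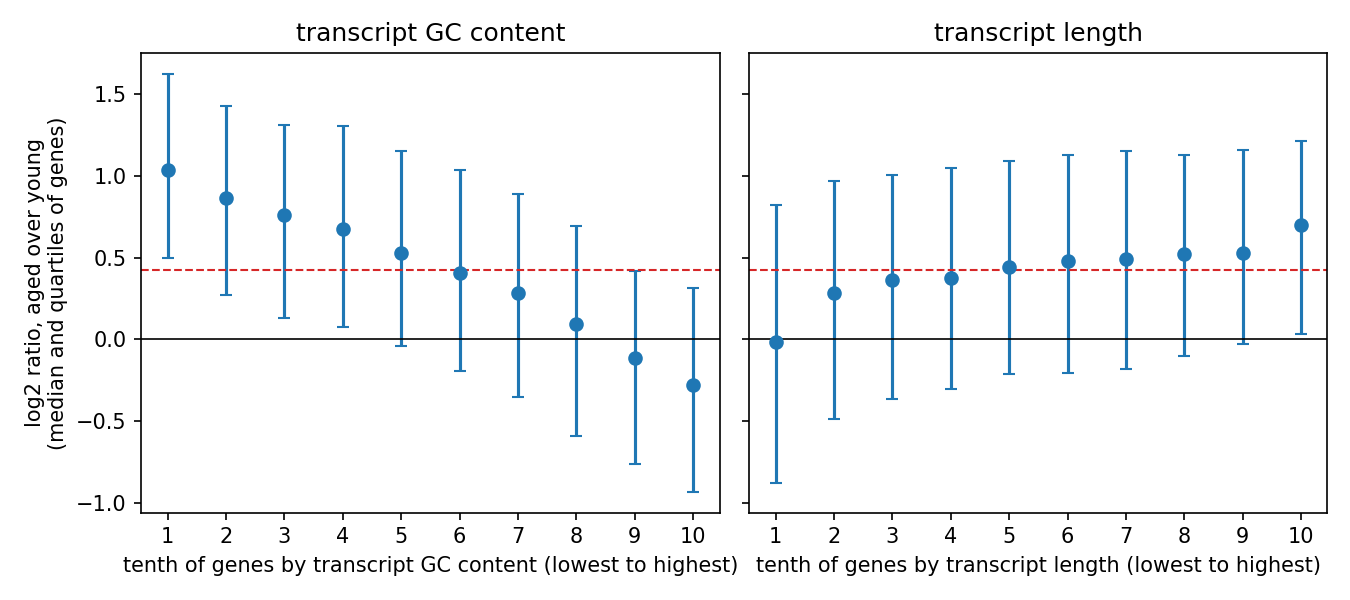
Median log2 ratio of aged over young (points) with quartiles of genes (bars) for 10 groups of genes ordered by transcript GC content (left) and length (right). The medians run from 1.04 in the lowest to −0.28 in the highest decile of GC content, and from −0.01 to 0.70 with length. The dashed line is the median gene at 0.43.

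Bub1b (ENSMUSG00000040084, chromosome 2), which encodes the spindle checkpoint protein BubR1, was 2.18-fold lower in the aged library (95% counting interval 2.14 to 2.23), with 674 CPM against 1472 CPM from 12526 and 28659 counts. Its log2 ratio was −1.13, and −1.55 relative to the median gene. Among the 200 genes nearest to it in mean count, 14 had a lower ratio, and the median of these neighbours was 0.02 with an SD of 0.87 across genes. Relative to these genes of similar level, the ratio of Bub1b was −1.14, less far from equality than relative to the median gene. Reduced by the median of its length and GC bin, its ratio was −1.54, and 11 of the 200 neighbours were lower. The authors' deposited table gives a log2 ratio of young over aged of 1.13 for Bub1b.

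The other genes of the spindle checkpoint, which delays anaphase until chromosomes are attached, did not share that difference. Of 16 members above the floor, 4 were at least 2-fold higher in the aged library and Bub1b was the 1 member at least 2-fold lower. Trip13, an ATPase that remodels Mad2, was 3.25-fold higher (28 and 87 counts), the checkpoint kinase gene Ttk 2.43-fold higher and Bub3, whose product binds BubR1, 2.37-fold higher. Relative to the median gene, only Trip13 remained at least 2-fold higher. The list's median of 0.41 was −0.02 relative to the median gene, and it stood at percentile 48.7 of random lists matched on mean count and 28.2 of those matched also on length and GC content. The median was also close to 0 with TMM scaling, at 0.03. The 27 kinetochore and centromere genes did not stand apart either, with 6 higher and 3 lower (2 and 5 relative to the median gene) and a median of 0.39 (−0.04 relative to the median gene, percentiles 45.8 and 9.71). Ska1 and Nuf2, both of the kinetochore's microtubule-binding interface, were 3.48-fold and 2.86-fold higher, while Cenpb, which binds centromeric satellite DNA, was 3.22-fold lower (64 and 19 counts). The list of the chromosomal passenger complex, which corrects attachments, also holds the kinase genes Haspin and Aurka, which are not subunits of that complex. Of the list's 7 genes, 2 were at least 2-fold higher and none lower (1, Haspin, and 0 relative to the median gene). The 2 higher genes were Haspin, at 3.44-fold, and Birc5, which encodes survivin, at 2.56-fold, while Aurkc, the germ-cell Aurora kinase, was 1.68-fold higher. The median of 0.12 became −0.31 relative to the median gene and stood at percentiles 36.0 and 34.8.

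**Figure D3:**
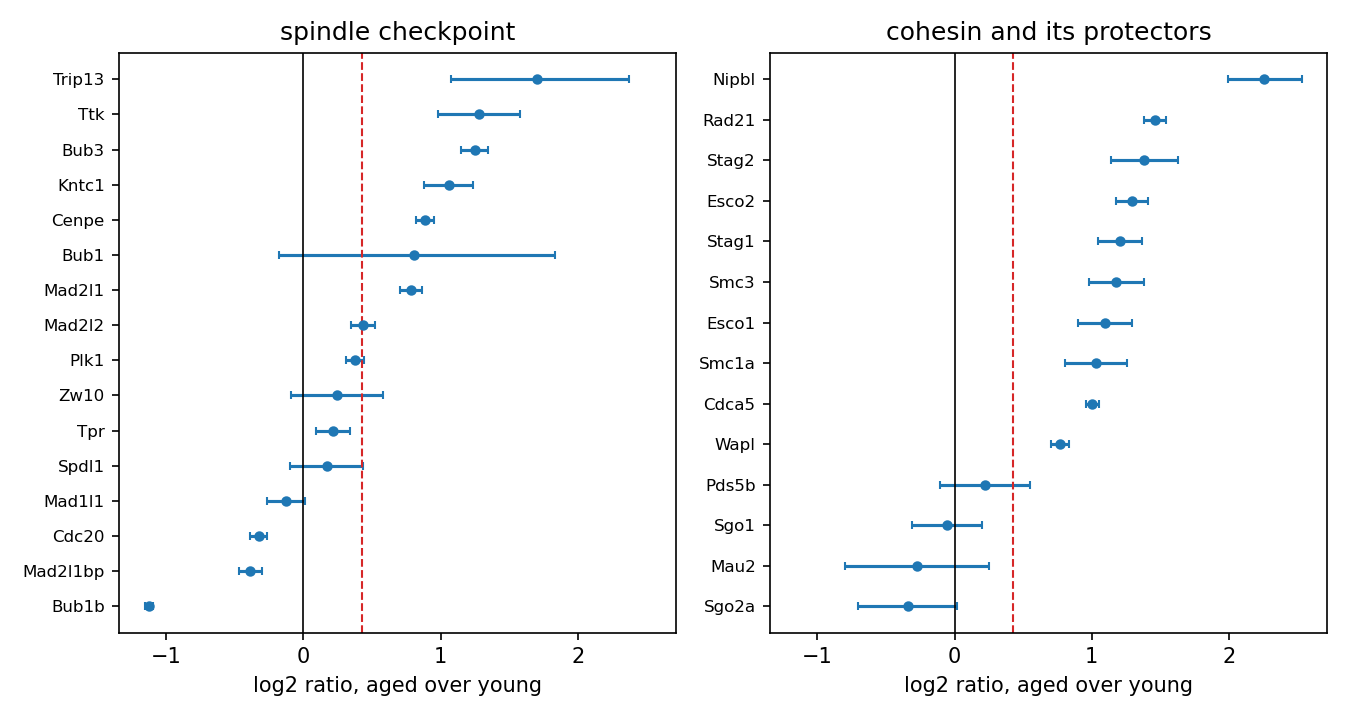
Log2 ratio of aged over young (x axis) for the 16 spindle checkpoint genes (left) and the 14 cohesin genes (right) with a mean of at least 20 counts, with 95% counting intervals as bars. The dashed line is the median gene at 0.43. Bub1b, at −1.13, has the lowest value of the left panel, and Nipbl, at 2.26, the highest of the right panel.

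Cohesin genes, whose products hold sister chromatids together, were mostly higher in the aged library. Of 14 members above the floor, 9 were at least 2-fold higher and none at least 2-fold lower, with a median of 1.06 (0.64 relative to the median gene, where 2 members were at least 2-fold higher). The cohesin loader gene Nipbl was 4.78-fold higher, Rad21, a kleisin subunit, 2.75-fold higher and Stag2 2.61-fold higher. The list stood at percentile 99.1 of random lists matched on mean count but at 82.5 of lists matched also on length and GC content, within the range of random lists, its members' median GC content being 41.7%. Meiosis-specific subunits lay below the floor, with 1 and 0 counts for Rec8, 4 and 0 for Rad21l, 4 and 15 for Stag3 and 15 and 24 for Smc1b in the young and aged libraries. These were chosen after their values were seen. Synaptonemal complex and recombination genes, which act earlier in prophase, had 10 members above the floor, of which none was at least 2-fold higher and 3 were lower, also relative to the median gene. Tex12, a synaptonemal central element gene, was 10.7-fold lower (213 and 19 counts), Psmc3ip 5.09-fold lower and Mei4 2.13-fold lower (29 and 13 counts). Their median of 0.20 was −0.23 relative to the median gene, at percentiles 33.3 and 9.51.

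Genes of the anaphase-promoting complex and MII arrest differed in both directions. Of 35 members, 6 were at least 2-fold higher and 4 lower (4 and 6 relative to the median gene), with a median of 0.14 (−0.29 relative to the median gene, percentiles 11.3 and 5.70). Beside Pttg1, Mastl, a kinase of meiotic maturation, was 3.29-fold higher, and Cdk1, the catalytic subunit of maturation-promoting factor, was 6.79-fold lower with 128 and 18 counts. The median of the spindle tubulin and motor genes was −0.15 (−0.58 relative to the median gene), at percentile 0.21 of count-matched lists and below every one of the 10000 lists matched on length and GC content, although 6 of 36 members were at least 2-fold higher and 5 lower (1 and 9 relative to the median gene). Tacc3, a spindle microtubule stabiliser, was 6.78-fold lower, Tuba4a 4.15-fold lower and the kinesin gene Kif2a 3.08-fold higher. Genes with the symbol stem Kif, nearly all kinesins and not all of the spindle, were chosen after the data were seen and did not share the low median, with 10 of 27 at least 2-fold higher, none lower and a median of 0.76 (0.33 relative to the median gene, percentiles 91.6 and 92.9).

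All 13 members above the floor of the list of mitochondrial genome transcripts, which holds messenger and ribosomal RNAs, were at least 2-fold higher in the aged library, 12 of them also relative to the median gene, with a median log2 ratio of 1.82 (1.39 relative to the median gene). All genes of the mitochondrial chromosome together took 1.62% of the counts in the aged library and 0.490% in the young one. The complex I gene mt-Nd3 was 8.60-fold higher (14 and 115 counts), mt-Co3, of cytochrome c oxidase, 6.76-fold higher (31 and 200 counts) and mt-Rnr1, the small ribosomal RNA, 4.49-fold higher (6346 and 27194 counts). The list's median lay above every count-matched list and at percentile 99.99 of those matched on length and GC content, although the matched genes had a median GC content of 42.1% against 36.0% in the list. Among random lists from 67 nuclear genes with a median GC content of 36.1%, not matched on mean count, the list stood at percentile 97.0, inside the range. Of 70 nuclear genes of oxidative phosphorylation, 22 were at least 2-fold lower, 9 at least 2-fold higher and 39 within 2-fold (29 lower and 5 higher relative to the median gene), with a median of −0.50 (−0.93 relative to the median gene). That median lay below every one of the random lists of either kind. The complex I subunit genes Ndufa7, Ndufc1 and Ndufa2 were 21.8-fold, 16.0-fold and 15.2-fold lower, with 2116 and 133 counts for Ndufa2. Among 20 abundant transcripts of somatic cells the median log2 ratio was −0.12, below the median gene at 0.43. They were not matched on mean count, length or GC content. Of 21 such transcripts with 20 or more counts in the young library, 5 were at least 2-fold lower in the aged library and 2 higher. Members lay in both directions, such as Tpt1 at −2.23, B2m at −0.85, Eef2 at 1.14 and Arpc1b at 1.89.

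Genes of mitochondrial dynamics and upkeep were higher, with 9 of 21 members at least 2-fold higher and 1 lower (6 and 2 relative to the median gene) and a median of 0.96 (0.53 relative to the median gene, percentiles 98.0 and 99.4). Hspa9, the mitochondrial Hsp70, was 6.28-fold higher and Opa1, of inner membrane fusion, 4.89-fold higher, while the import pore gene Tomm40 was 8.40-fold lower (44 and 5 counts). The list no longer stood apart with 5 counts added (97.0), with no floor (96.1) or with a floor of 100 counts (43.7). Antioxidant genes did not stand apart, with 5 of 25 higher and 1 lower (3 and 3 relative to the median gene) and a median of 0.47 (0.04 relative to the median gene, percentiles 60.1 and 69.1). The members furthest from equality were Gsta4, 5.5-fold higher, and the peroxiredoxin genes Prdx6 and Prdx1, 4.85-fold and 4.76-fold higher.

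Ribosomal protein genes had the lowest median of the 22 lists. Of 57 members, 23 were at least 2-fold lower in the aged library and 5 higher (29 and 3 relative to the median gene), with a median of −0.62 (−1.04 relative to the median gene), below every random list of either kind. Rps9 was 9.43-fold lower, Rps19 7.64-fold lower and Rplp1 5.52-fold lower, with 4227 and 731 counts for Rplp1. A further 30 members lay below the floor or had no counts, and reads of these genes can be shared with their many pseudogenes. The somatic transcripts named with oxidative phosphorylation, at −0.12, and Vim, with 51 and 0 counts, apply here too, as other cells also express these genes. Proteasome genes were higher, with 13 of 27 members at least 2-fold higher and 2 lower (5 and 2 relative to the median gene), a median of 0.88 (0.46 relative to the median gene) and percentiles of 98.6 and 98.4. The list no longer stood apart with no floor (96.5) or without matching on expression (97.4), and its 5 members below the floor were all lower in the aged library, from 38 and 1 counts for Psmb7 to 25 and 5 for Psmd14, chosen after their values were seen. Psma3 was 3.98-fold higher (10 and 38 counts), Psmd11 3.59-fold and Psma6 3.53-fold. Chaperone and heat shock genes were similar in size, with 13 of 27 higher, 2 lower (5 and 2 relative to the median gene) and a median of 0.91 (0.49 relative to the median gene). They stood at percentile 98.4 of count-matched lists and at 95.03, within the range, when length and GC content were matched, and were also within it with 5 counts added (97.49) and with a floor of 100 counts (79.0). The chaperonin gene Cct8 was 6.29-fold higher and Hsf1, the heat shock transcription factor, 5.02-fold lower.

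The list of zona pellucida and oocyte-secreted genes had a low median in the aged library. It also holds other oocyte genes, such as H1foo, Figla and the Obox genes. None of 23 members was at least 2-fold higher and 6 were lower (11 relative to the median gene). The median was −0.57 (−0.99 relative to the median gene), below every count-matched list and at percentile 0.01 of lists matched on length and GC content. The list held 3888551 counts in the young and 2092890 in the aged library, and its most abundant members were matched with less abundant genes. The 100 most abundant genes also took a smaller share of the aged library, 40.6% against 51.1%. A general loss among the most abundant genes is therefore not excluded. Besides Gdf9 and Oosp1, Figla, the transcription factor that drives zona genes, was 7.87-fold lower (206 and 25 counts), Omt2b 2.89-fold lower and Obox5 2.5-fold lower. Maternal effect genes, including those of the subcortical maternal complex, did not stand apart, with 8 of 23 higher and 2 lower (3 and 4 relative to the median gene) and a median of 0.55 (0.13 relative to the median gene, percentiles 84.6 and 81.9). Nlrp4f was 3.73-fold and Nlrp9a 3.40-fold higher, and both belong to a family with close copies. Genes of maternal mRNA storage and decay split, with 10 of 30 at least 2-fold higher and 4 lower (4 and 8 relative to the median gene). Lsm14b was 7.49-fold higher, with 8720 CPM against 1164 CPM, and the translational regulator gene Dazl 4.37-fold higher, while the deadenylase gene Cnot8 was 3.86-fold lower. Their median of 0.36 was −0.06 relative to the median gene, at percentiles 58.1 and 22.7.

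Chromatin and repair genes did not stand apart from random lists. DNA methylation and imprint protection genes had a median of 0.14 (−0.29 relative to the median gene, percentiles 18.97 and 27.7), with 4 of 16 higher and 1 lower (1 and 2 relative to the median gene). The hemimethylation reader gene Uhrf1 was 2.67-fold higher, the glycosylase gene Mbd4 3.64-fold higher and Dmap1 5.23-fold lower. Histone deacetylase, sirtuin and acetyltransferase genes had a median of 0.68 (0.25 relative to the median gene, percentiles 79.5 and 91.3), with 3 of 18 higher and 2 lower (3 and 3 relative to the median gene). Hdac2 was 3.26-fold and the acetyltransferase gene Hat1 3.13-fold higher, and the sirtuin gene Sirt2 was 22.4-fold lower with 47 and 2 counts (95% counting interval 5.88 to 191). Double-strand break repair genes had a median of 0.66 (0.24 relative to the median gene, percentiles 85.6 and 51.9), with 8 of 27 higher and 1 lower (5 and 2 relative to the median gene). Rad52 was 9.62-fold higher (16 and 147 counts), Xrcc4 3.92-fold and Mre11a 3.78-fold.

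**Figure D4:**
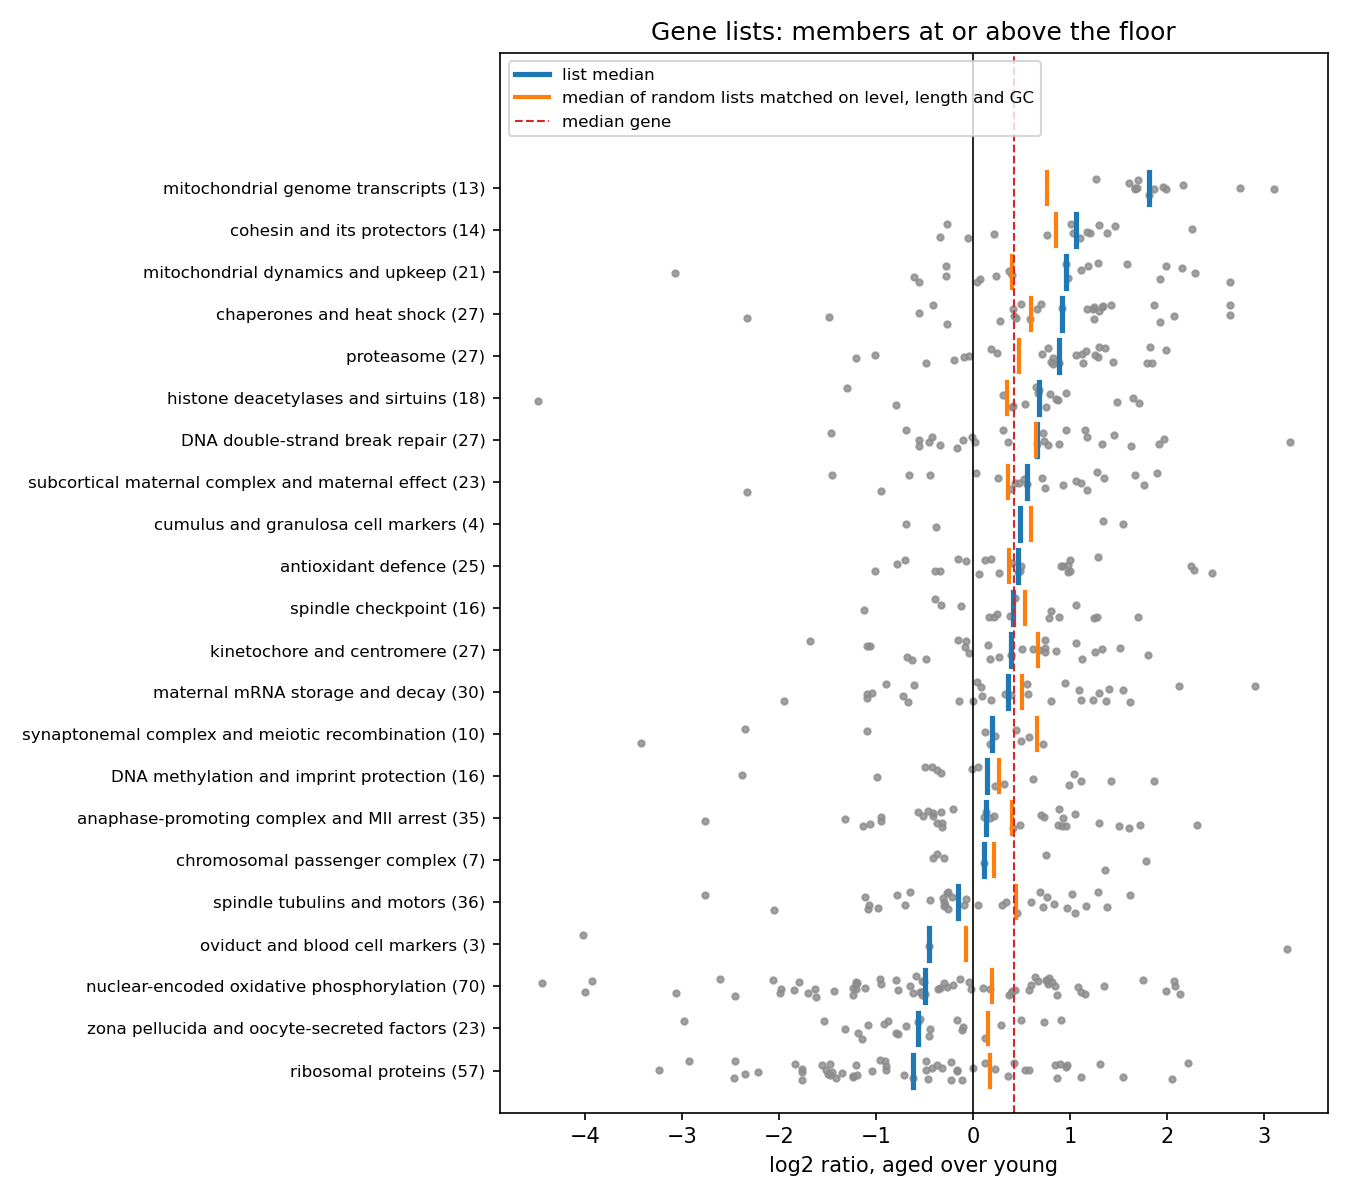
Log2 ratio of aged over young (x axis) of the members of each of the 22 gene lists with a mean of at least 20 counts, their number in parentheses. Blue bars are list medians, orange bars the median of random lists matched on mean count, length and GC content, and the dashed line is the median gene at 0.43. The medians run from −0.62 for ribosomal proteins to 1.82 for mitochondrial genome transcripts.

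Few of the fixed markers of other cell types reached the floor. Of 30 cumulus and granulosa cell markers, 4 reached the floor, 2 of them at least 2-fold higher in the aged library and none lower (1 and 1 relative to the median gene), with a median of 0.48 (0.06 relative to the median gene, percentiles 53.0 and 40.5). Cyp19a1, which encodes aromatase, was 2.54-fold higher (436 and 1056 counts), Nr5a2 2.92-fold higher and Col4a1 1.62-fold lower. Among the markers below the floor, chosen after their values were seen, Cyp11a1 had 27 and 1 counts, Hsd3b1 18 and 6 and Inha 14 and 0. Fst had 14 and 0 counts and Gja1 11 and 0, while Fshr, with 0 and 16, and Has2, with 0 and 2, went the other way. With no floor the list stood at percentile 1.27. Of the oviduct and blood cell markers 3 reached the floor, 1 at least 2-fold higher and 1 lower, with a median of −0.46 (−0.89 relative to the median gene, percentiles 21.8 and 35.4). Vim, a cytoskeletal gene of mesenchymal cells, had 51 and 0 counts. Against 3 counts it was at least 16.2-fold lower, and its counting interval began at 12.7-fold. Acta2 was 9.42-fold higher (4 and 36 counts) and C1qb had 36 and 25 counts.

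The genes with the highest ratios, by the bound of the interval nearest to equality, included Tceal8, 46.9-fold higher with 36 and 1611 counts, the receptor tyrosine kinase gene Mertk, 38.3-fold higher with 51 and 1864, and the mitochondrial transfer RNA genes mt-Ta, 50.3-fold higher with 19 and 913, and mt-Tq, 35.8-fold higher with 159 and 5439. Xdh, which encodes xanthine dehydrogenase, had 2 and 223 counts, a ratio of 117 (95% counting interval 31.9 to 970). The intervals also lay far from equality for Cyp4a14, with 1 and 103 counts (18.9-fold to 4301-fold higher), and Atp8a2, with 1 and 86 counts (15.7-fold to 3598-fold higher). With no count in the young library, and against 3 counts, the nucleolar RNA gene Snord100 was at least 38.05-fold higher, the embryonic myosin gene Myh3 at least 30.7-fold and Scarna6 at least 26.2-fold. Their 95% counting intervals began at 30.4-fold, 24.5-fold and 20.8-fold. Among the lowest, S100a6, which encodes a calcium-binding protein, had 349 counts in the young library and none in the aged one. Against 3 counts it was at least 111-fold lower (95% counting interval from 89.9-fold). Spp1, which encodes osteopontin, had 234 and 1 counts, a level 223-fold lower (95% counting interval 39.7 to 8863), and Gpn2 had 208 and 2 counts, 99.3-fold lower (27.1 to 826). Cyth1 was 37.3-fold lower with 859 and 22 counts. No count was left in the aged library for Zfp524 (120 in the young), Coq8b (115), Timp1 (108), Lyrm9 (104), Nat9 (95) and Nupr1 (91). Against 3 counts they were at least 38.2-fold, 36.6-fold, 34.4-fold, 33.1-fold, 30.2-fold and 29.0-fold lower. Their 95% counting intervals began at 30.6-fold, 29.3-fold, 27.5-fold, 26.4-fold, 24.1-fold and 23.1-fold.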

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

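The comparison with length and GC content, as a matching of lists and as a correction of genes, was chosen after the data were seen. Leaving out a replicate was not possible with 1 library per age. No paired analysis was possible because each age has 1 library and no test was run. Depth limits the genes near the floor, and the pools rather than depth limit what can be said of age. Where no reason is given for a change below, the cause was not tested.

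Scaling decided the balance of higher and lower genes, since it shifts all ratios by 1 value (−0.43 by median-centring, −0.37 by TMM, −0.29 by leaving out the 100 most abundant genes). Against 2844 genes at least 2-fold higher and 1081 lower in the aged library (1841 and 648 beyond the interval), median-centring gave 1633 and 1766 (890 and 1167) and TMM 1757 and 1668 (977 and 1078). Totals without the 100 most abundant genes gave 1133 higher beyond the interval. The log2 ratio of Bub1b was −1.55, −1.50 and −1.41 with these scalings, and −1.54 less the median of its length and GC bin, against −1.13. Relative to the median of the 200 genes nearest in mean count it was −1.14. The length and GC correction also shifts the median gene by −0.43, so its values compare with those of median-centring. That correction left 1345 genes higher, 688 of them beyond the interval. More or fewer genes pass other limits by construction. Without a floor 4619 were higher and 2403 lower, 1015 of these beyond the interval, and with a floor of 100 counts 1727 and 496, with 353 lower beyond the interval. At 1.5-fold there were 4424 and 1744 (3184 and 1145 beyond the interval) and at 4-fold 680 and 352 (269 and 195). Genes detected were 16317 in the young and 16406 in the aged library at any count, and 6326 and 6787 at 100 counts. Counts with 0.5 or 5 counts added and with rows summed by symbol stayed within 1.5 times, as did the authors' calls at the stricter q-value.

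Of the 22 lists, 20 kept their side of the range when length and GC content were matched. The exceptions were cohesin, at percentile 82.5, and chaperones, at 95.03, where the matched genes themselves had higher ratios. Mitochondrial dynamics and upkeep fell inside the range with 5 counts added (97.0) and no floor (96.1), and to 43.7 with a floor of 100 counts, where fewer members remain. Proteasome genes were inside it with no floor (96.5) and without matching on expression (97.4). Chaperones were inside it with 5 counts added (97.49) and with a floor of 100 counts (79.0). Cumulus and granulosa markers fell below it with no floor (1.27). No oviduct or blood cell marker reached a floor of 100 counts, so that list has no value there. With 0.5 counts added or rows summed by symbol, no list crossed the limits.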

Other observations

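The gene families, transcript types and chromosomes below, and the tests of a few abundant genes and of nuclear genes of low GC content, were chosen after the data were seen. Among 60 families of genes that share a symbol stem, the Trim ubiquitin ligase family was high in the aged library. Of its 26 members 12 were at least 2-fold higher and none lower, with a median log2 ratio of 0.99 (0.56 relative to the median gene) at percentile 99.1 of random lists matched on mean count, length and GC content. The Fbxw family of substrate receptors of ubiquitin ligases followed, with 10 of 19 higher, 1 lower, a median of 1.05 (0.62 relative to the median gene) and percentile 98.8. The 161 zinc finger genes named Zfp stood at percentile 98.0 of count-matched lists but at 82.3 with length and GC content matched. On the low side, beside ribosomal protein genes, mitochondrial ribosomal protein genes (Mrpl) stood at percentile 0.82, with a median of −0.12 (−0.54 relative to the median gene) although 11 of 46 were at least 2-fold higher and 9 lower. The 29 genes of the other mitochondrial ribosomal subunit (Mrps) did not stand apart, with a median of 0.47 (0.04 relative to the median gene) and percentile 68.3. Cox genes, of cytochrome c oxidase and its assembly and partly in the oxidative phosphorylation list, stood at 2.25, with a median of −0.34 (−0.77 relative to the median gene), none of 19 at least 2-fold higher and 5 lower. The 19 Taf genes of general transcription factors stood at 0.39 there but at 2.57 of count-matched lists, inside the range, with a median of −0.04 (−0.47 relative to the median gene) and with 6 members at least 2-fold higher and 3 lower. Of the 60 families 7 (11.7%) lay outside the range with length and GC content matched, among them Rps and Rpl. With mean count alone 9 did so, where 5% of lists of genes drawn singly at random would lie outside. Members of a family can vary together, so neither number measures an excess over chance.

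All 13 mitochondrial transfer RNA genes above the floor were at least 2-fold higher in the aged library, with a median of 2.70, and so were 17 of 29 small nucleolar RNA genes, with 2 lower and a median of 2.07. Both medians lay above every count-matched list, and at percentiles 99.8 and 100 with length and GC content matched. That match was poor, since the matched genes had a median length of 306 bases against 69 for the transfer RNAs, with a GC content of 43.9% against 34.8%, and 321 against 135 bases for the nucleolar RNAs, so length and, for the transfer RNAs, GC content are not excluded. Of the 275 processed pseudogenes 57 were at least 2-fold higher and 63 lower, with a median of 0.04 (−0.39 relative to the median gene), below every count-matched list and at percentile 0.72 with length and GC content matched, where the matched genes were longer (766 against 519 bases). Over the nuclear chromosomes, medians ran from 0.18 on chromosome 17 to 0.76 on the X chromosome, but from −0.08 on chromosome 8 to 0.05 on chromosome 2 after each gene was reduced by the median of its length and GC bin. The 27 genes of the mitochondrial chromosome had 2.17 and 0.98. Several genes that most cells use had few counts in both libraries, among them Actg1 with 4 and 4, Gapdh with 7 and 8 and Hspa8 with 1 and 31.

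The medians of nuclear oxidative phosphorylation and ribosomal protein genes were low in the aged library, at −0.50 and −0.62. Transcript length and GC content as the whole cause are argued against, since the percentile was 0 for both lists among random lists matched on them. The matched genes were longer, however, with median lengths of 1077 against 913 bases for oxidative phosphorylation and 1059 against 943 for ribosomal proteins. Length is also that of the longest annotated transcript, so a contribution of length is not excluded. RNA of somatic cells in the young library stays open. A panel of 20 abundant somatic transcripts had a median of −0.12 (95% bootstrap interval −0.61 to 0.27), between the lists and the median gene at 0.43. The panel was not matched on mean count, length or GC content, and oocytes may carry many of its transcripts. Its median therefore cannot decide whether somatic RNA was present. The interval of the panel's median less the list's was −0.30 to 0.79 for oxidative phosphorylation and −0.13 to 1.18 for ribosomal proteins; the bound first set for ribosomal proteins, that the panel's interval should lie above −0.62, was met but left out the spread of the list itself. Age, sharing of reads with pseudogenes and a difference between the amplifications were not tested and could each contribute, with 1 library per age.

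Transcripts of the mitochondrial genome were high in the aged library. A few genes taking most of the counts in the young library would lift all others by 1 factor. This is argued against as the whole cause by the list's median of 1.82 (95% bootstrap interval 1.67 to 1.98) against 0.43 for all genes. The lowest of the 13 members lay at 1.27. The bootstrap interval is over transcripts of 1 genome, which are not independent, and holds no spread between libraries. GC content stays open in part, because the list stood at percentile 99.96 of nuclear lists matched on count and GC content, whose median was 0.92, but those genes had a median GC content of 39.9% against 36.0%. Random lists from 67 nuclear genes of at most 37% GC (median 36.1%), not matched on count, had the list at percentile 97.0, just inside the range, their median being 1.09. A difference with age, such as more mitochondrial RNA per oocyte, is a hypothesis that was not tested.

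S100a6, Spp1, Timp1 and Vim, which many somatic cells express, had 349, 234, 108 and 51 counts in the young library and 0, 1, 0 and 0 in the aged one. If cells of one somatic type had entered the young pool, at least 50% of the genes of its marker panel should have 20 or more counts there. These genes should also be at least 2-fold lower in the aged library. The highest share with 20 or more young counts among the panels of single cell types was 37.5%, for macrophages. That bound may be too strict for a small admixture, since the panel of granulosa, cumulus and luteal genes held 520 counts in the young and 98 in the aged library, 120 and 27 without Fdx1 and 74 and 27 also without Scd1, although Cyp19a1 (436 and 1056 counts), Nr5a2 (38 and 106) and Fshr (0 and 16) of the same cells were higher in the aged library. The other panels held 243 and 166 counts (fibroblasts), 1044 and 1099 (macrophages), 6294 and 6034 (epithelium) and 1200 and 1830 (endothelium). Blood cell genes held 1897 and 3268, and abundant somatic transcripts 17694 and 26326. Of the 30 abundant transcripts, 20 also had 20 or more counts in the aged library, so that oocytes may carry them. A large part of some totals was 1 gene, Cdh1 (4678 and 5175, epithelium), Srgn (1785 and 3180, blood cells) or Arpc1b (3911 and 13871, abundant transcripts). Of 4 fibroblast genes with 20 or more young counts, 2 were at least 2-fold lower and 1 higher. These numbers were 1 and 0 of 6 (macrophages), 2 and 0 of 4 (epithelium) and 1 and 2 of 5 (endothelium). They were 3 and 0 of 3 (granulosa, cumulus and luteal) and 0 and 0 of 2 (blood cells). Cells of one somatic type in the young pool are thus neither shown nor excluded, and cannot be told apart from a difference with age in these 2 libraries.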
